A study of Homo sapiens with 9 samples.

How the data were processed

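The series measured messenger RNA in 3 cultured human cell lines: TIG-1, a line of lung fibroblasts, and YST-1 and HS-PSS, whose cell type label is schwannoma, a tumour of Schwann cells, the cells that ensheath peripheral nerves. The tissue label of HS-PSS is prostate. Each line had 1 control library and 1 library each from cells exposed for 7 days to 10 or 30 µM of a compound the labels abbreviate PER. It is read here as perampanel, an antagonist of AMPA-type glutamate receptors, because the title of the series is about blocking calcium-permeable receptors of that type. The labels state no day for the controls. Groups were taken from the sample titles, which gave 9 groups of 1 library.

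Per the labels' protocols, RNA was enriched with poly-T beads and made into strand-marked libraries with dUTP in the second strand. The submitters' processing notes name cutadapt, a read trimmer, Salmon, a transcript quantifier, and the builds GRCh38 and hg38. The versions, the annotation and the handling of strand are not given in the sources used here. The authors deposited 1 table of estimated counts, not normalized, for 28431 gene symbols and 9 libraries. All values were whole numbers, so rounding changed nothing. An estimate of this kind shares reads among transcripts by a model, so genes with close copies, overlapping genes and read-through transcripts can lose or gain counts together. Of the symbols, 27959 matched the NCBI RefSeq gene table of GRCh38.p14, which was used for gene positions, including those of the MHC region (chromosome 6, 28000000 to 34000000).

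Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood F test) and Benjamini-Hochberg adjustment over all tested genes, with a threshold of 0.05. The first model had the line and the dose as factors and 4 residual degrees of freedom, so the lines served as the replicates of a dose. The second model gave the fibroblast line and the schwannoma lines their own dose terms and had 2 residual degrees of freedom. From these came 7 contrasts of dose and of the difference between cell types, and 3 contrasts between lines. Nothing states that the libraries come from separate cultures, so p-values measure only the spread between these samples, which may be technical. Within a line, a log2 ratio of CPM (counts scaled to a common library size with TMM factors) with a prior count of 2 was computed for genes at 10 CPM or more in at least 1 of the 2 libraries. These ratios rest on 1 library against 1, have no replicate check and carry no p-value.

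Gene lists, 31 in number, cover glutamate receptors, cell division, stress and metabolic responses, signalling outputs and markers of the lineages the cells could belong to. Each was tested with camera from limma 3.58.1 at an inter-gene correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation and with fry, which tests whether the genes of a list move, on balance, one way. Within a line a list's median is given with its percentile among 10000 random lists of the same size matched on mean expression, as a description of those libraries.

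The models, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule takes, per dose contrast, up to 10 genes each way among those past the threshold, with the same sign in every line of the contrast and 5 CPM or more in at least 3 libraries. Where none pass, it takes the 5 genes each way with the smallest p, as values only. Differences between cell types take the 5 largest each way without the sign condition, ratios within a line the 5 largest each way at 30 µM, and lists up to 4 members with the smallest p. Line differences name members of the lineage lists. GRIA1, GRIA2, GRIA3, GRIA4, ADARB1, MKI67, TOP2A, CCNB1, CDK1, CDKN1A, SOX10, S100B and NF2 are always given per library. Genes named outside the rule are said to have been chosen after their values were seen. Confidence intervals are at 95%: exact Poisson limits for a CPM and exact conditional binomial limits for a ratio of 2 libraries. A count of 0 is set against a floor of 3 counts per library. Intervals and floors cover counting error only.

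The alternatives were DESeq2 size factors, no filter on low counts, DESeq2 1.42.0, limma voom, no line term, fits to fewer libraries, a linear dose, each line and each library left out in turn, a prior count of 0.5 and a floor of 1 CPM. After the data had been seen, 3 choices were added: ratios of 30 against 10 µM within a line, ratios for genes at 10 CPM or more in both libraries, and fits without the library labelled HS-PSS control that also leave out genes counted at 0 to 3 in 1 library of a line and at 50 or more in another library of that line, that library not counted (on/off genes below). The wider use of fits without the library labelled HS-PSS control was also decided after the data had been seen.

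The gene test was tested on simulated data for the contrast of 30 µM with control over the 3 lines, with 200 genes changed. When the simulated HS-PSS control had the HS-PSS profile, 92% of the genes changed 2-fold were recovered among 15045 tested. When it had the YST-1 profile, 2% were recovered among 15051 tested with 9 libraries, and 90% among 15020 with that library left out. These shares hold for the simulated data only. With that library left out, HS-PSS bears on this contrast only through 30 µM against the lower dose. Real genes that change alike at both doses therefore gain little from HS-PSS, and the 90% need not hold for them. Figures were drawn with python 3.11.15 and matplotlib 3.10.9.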

Results

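Messenger RNA was counted in 9 libraries from TIG-1 fibroblasts and from the lines YST-1 and HS-PSS, labelled schwannoma, as control cells or after 7 days with 10 or 30 µM of the compound. Library totals ran from 24308090 counts (TIG-1 control) to 32670223 (YST-1 at 10 µM). Between 16167 and 16625 genes had at least 1 count. There was 1 library per line and dose, so no single line and dose has a measured error.

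The libraries differed in which AMPA receptor subunits they held. In TIG-1, GRIA1 stood at 9.15, 7.44 and 8.14 CPM and GRIA3 at 16.1, 17.0 and 16.0 CPM (control, 10 and 30 µM). GRIA2, the subunit whose edited form keeps AMPA receptors from passing calcium, had 0 counts in TIG-1 at control and 10 µM and 3 counts at 30 µM, where 3 counts equal 0.118 CPM. In YST-1, GRIA2 stood at 344, 367 and 365 CPM and GRIA4 at 3.27, 3.78 and 4.40 CPM, while GRIA1 and GRIA3 had 0 counts, with a 95% upper limit of 0.120 CPM in the control. In HS-PSS at 10 and 30 µM, GRIA1 stood at 5.04 and 5.48 CPM, GRIA2 and GRIA3 had 0 counts, and GRIA4 had 0 and 2 counts. The library labelled HS-PSS control held GRIA2 at 366 CPM and GRIA4 at 4.66 CPM, and GRIA1 at 0 counts. ADARB1, which encodes an enzyme that edits the GRIA2 transcript, stood at 63.3, 53.1 and 34.2 CPM in TIG-1 at 29.3, 25.8 and 24.1 CPM in YST-1, at 25.7 CPM in the library labelled HS-PSS control and at 22.8 and 23.4 CPM in HS-PSS at 10 and 30 µM. GRIA4 in TIG-1 stood at 1.88, 2.37 and 2.95 CPM, and GRIA3 had 0 counts in the library labelled HS-PSS control. The genes lie at GRIA1 chromosome 5, 153489615 to 153813869, GRIA2 chromosome 4, 157220120 to 157366075, GRIA3 chromosome X, 123184278 to 123490915, and GRIA4 chromosome 11, 105609994 to 105982090 (GRCh38.p14). GRIA2 at 30 µM against control in YST-1 had a ratio of 1.06 (95% counting interval 1.04 to 1.09).

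**Figure D1:**
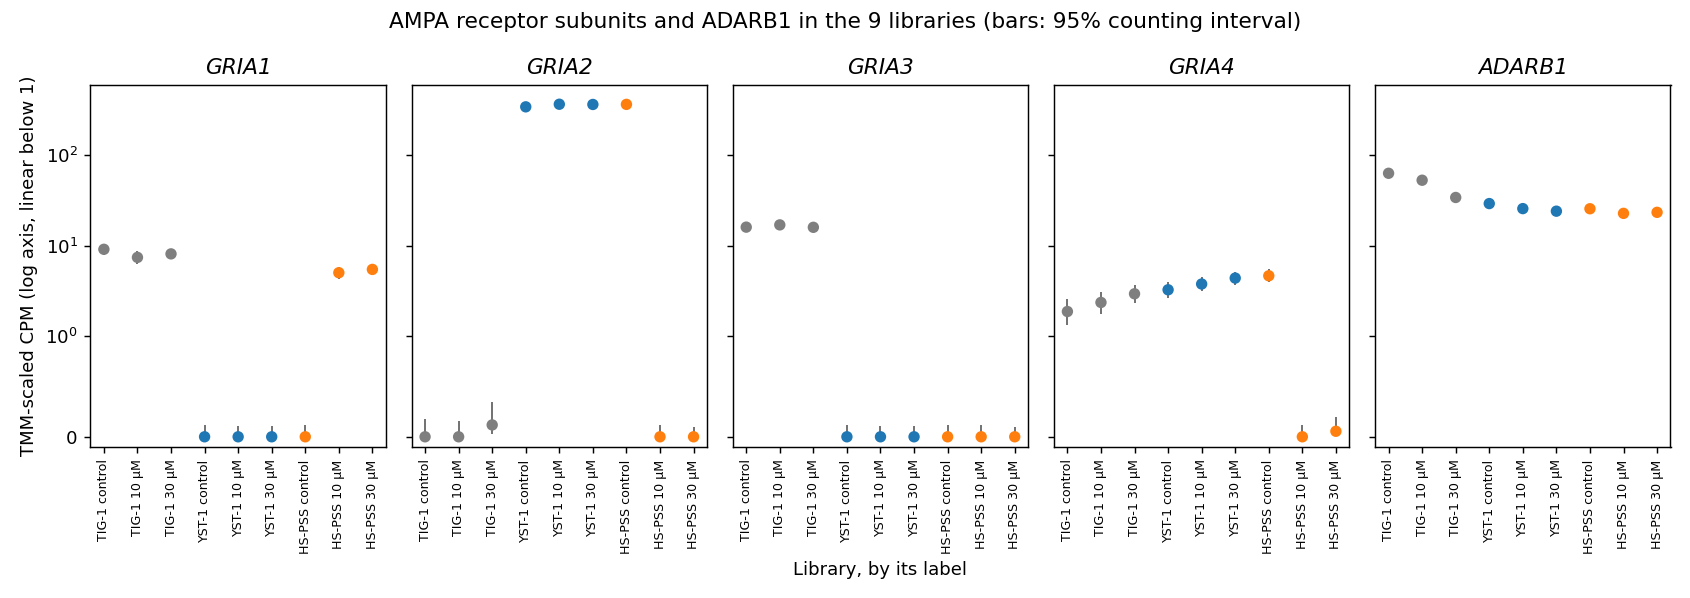
CPM of the AMPA receptor subunit genes and ADARB1 in each of the 9 libraries, on an axis that is logarithmic above 1 CPM and linear below it, with points coloured by line label and bars giving the 95% counting interval. GRIA2 lies between 344 and 367 CPM in the YST-1 libraries and at 366 CPM in the library labelled HS-PSS control, and had 0 counts in the HS-PSS libraries at 10 and 30 µM.

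Other genes chosen in advance gave the proliferation and lineage state per library, here in the order control, 10 and 30 µM, with the library labelled HS-PSS control as the first value for HS-PSS. MKI67, a marker of cycling cells, stood at 413, 382 and 449 CPM in TIG-1, at 411, 398 and 400 CPM in YST-1, and at 431, 773 and 743 CPM in HS-PSS. TOP2A, a topoisomerase of dividing cells, stood at 474, 474 and 547 CPM in TIG-1, at 603, 622 and 578 CPM in YST-1, and at 627, 488 and 470 CPM in HS-PSS. CCNB1, the cyclin of entry into mitosis, stood at 173, 163 and 193 CPM in TIG-1, at 92.7, 96.4 and 87.6 CPM in YST-1, and at 98.7, 154 and 149 CPM in HS-PSS. Its kinase CDK1 stood at 84.7, 92.0 and 103 CPM in TIG-1, at 119, 121 and 111 CPM in YST-1, and at 130, 196 and 198 CPM in HS-PSS. CDKN1A, an inhibitor of the cell cycle, stood at 327, 360 and 337 CPM in TIG-1, at 202, 200 and 197 CPM in YST-1, and at 191, 194 and 228 CPM in HS-PSS. NF2, the gene lost in many schwannomas, stood at 125, 117 and 122 CPM in TIG-1, at 60.2, 53.8 and 60.3 CPM in YST-1, and at 57.7, 61.1 and 66.4 CPM in HS-PSS. The Schwann cell gene SOX10 had 1 count in the TIG-1 control, 3 counts in the YST-1 control and 0 in the other libraries. S100B, another, stood at 0, 0 and 0.0787 CPM in TIG-1, at 0.261, 0.176 and 0.121 CPM in YST-1, and at 0.0630, 0.381 and 0.795 CPM in HS-PSS.

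The library labelled HS-PSS control did not resemble the other libraries of that line. Among genes chosen after their values were seen, the cell adhesion gene NCAM1 stood at 0.347 CPM there and at 618 and 571 CPM in HS-PSS at 10 and 30 µM, against 0 counts in the YST-1 control. L1CAM, another adhesion gene, stood at 192 CPM there, at 200 CPM in the YST-1 control, and had 3 and 2 counts in HS-PSS at 10 and 30 µM. CDKN2A, an inhibitor of the cell cycle, had 0 counts in the treated HS-PSS libraries, 17.5 CPM in the library labelled HS-PSS control and 21.8 CPM in the YST-1 control. Across genes at 10 CPM or more in both libraries, the SD of the log2 ratio was 0.0974 between that library and the YST-1 control and 0.978 and 0.971 between it and HS-PSS at 10 and 30 µM. Between YST-1 libraries it was 0.109 to 0.130. Pearson's r across genes, which are not independent replicates, was 0.999 with the YST-1 control and 0.885 with each treated HS-PSS library. Of 57 genes high in HS-PSS at 10 and 30 µM and near 0 in the YST-1 libraries, the median stood at 0.134% of the HS-PSS level in that library and at 0.0256 to 0.0320% in YST-1. The chi-square per gene of the counts against the YST-1 control was 4.12, and between YST-1 libraries 6.01 to 7.63, so these libraries differed by more than sampling noise and are not treated as 1 library. Results below are given with and without this library.

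**Figure D2:**
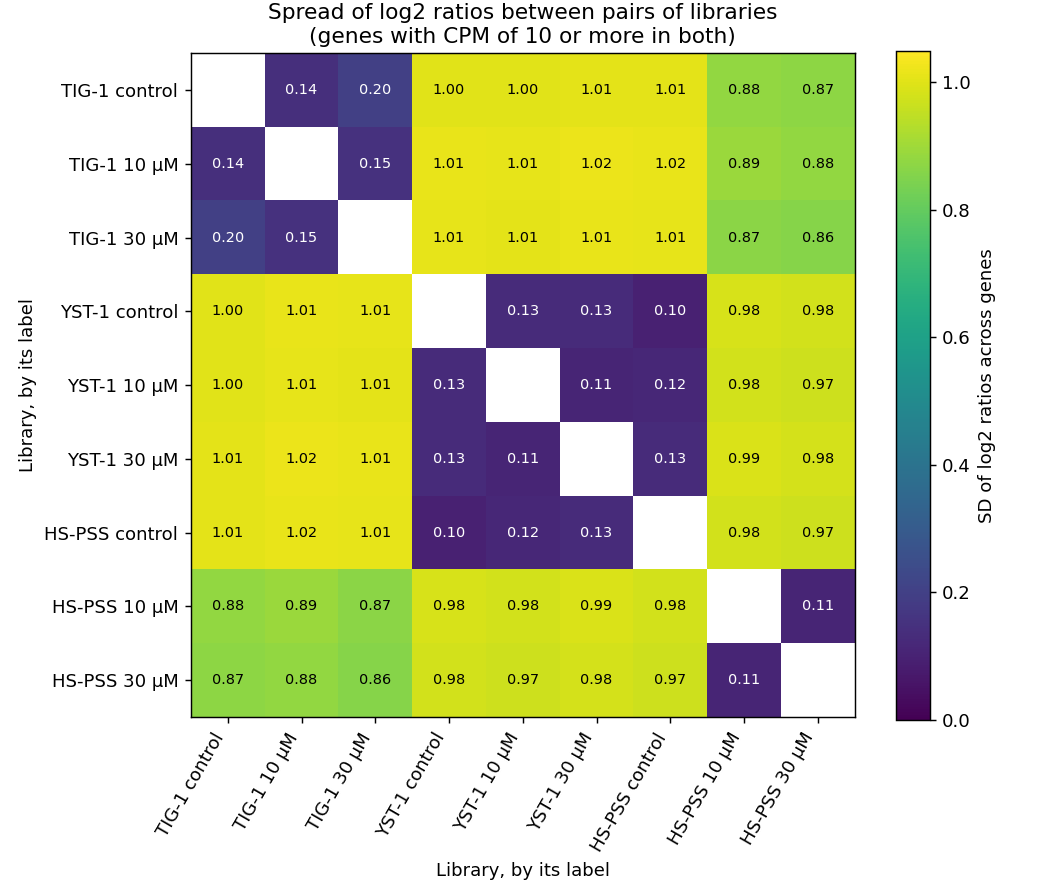
SD of log2 ratios across genes for each pair of the 9 libraries, with library labels on both axes and the SD as colour and number. The library labelled HS-PSS control lies at 0.0974 from the YST-1 control and at 0.971 from HS-PSS at 30 µM.

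Over the 3 lines, 30 µM against control estimated the average change of each gene. In the fit without the library labelled HS-PSS control, the controls are those of TIG-1 and YST-1, and HS-PSS enters through 30 against 10 µM only. TGM2, a transglutaminase that cross-links proteins, had a log2 fold change of -1.64 (SE 0.16, adjusted p = 0.0178, edgeR) and TFPI2, an inhibitor of serine proteases, of -0.67 (SE 0.07, adjusted p = 0.0178, edgeR) in the fit without the library labelled HS-PSS control, and each was lower at 30 µM in TIG-1 and YST-1. There NAPEPLD, a phospholipase D that releases N-acylethanolamines, passed with 0 counts in the TIG-1 and YST-1 controls. It had 251, 84 and 329 counts at 10 µM and 240, 104 and 351 counts at 30 µM in TIG-1, YST-1 and HS-PSS. The library labelled HS-PSS control, which is not in this fit, also had 0 counts. With on/off genes also left out, the rule took 12 genes. CEMIP, a hyaluronan-binding protein, fell by 1.89 (SE 0.28), CORIN by 1.45, TNFAIP2 by 0.87, the ligand WNT5A by 0.79, PLAT, the tissue plasminogen activator, by 0.73 and TMEM158 by 0.45 on the log2 scale, and TGM2 had an adjusted p of 0.00298. NDE1, a centrosomal protein, rose by 1.80 (SE 0.21), the actin-severing SCIN by 1.40, the matrix protein POSTN by 0.65 and the cadherin CDH6 by 0.57. NDE1 also stood 1.54 higher on the log2 scale in the library labelled HS-PSS control than in the YST-1 control. The gene overlaps MYH11, an on/off gene in TIG-1, so counts of NDE1 are uncertain here and below. CORIN and CEMIP stood at 55.6 and 376 CPM in the TIG-1 control and at 0.03 and 5.71 CPM in the YST-1 control, and TGM2 at 293 and 2.81 CPM, so these estimates rest mostly on TIG-1. POSTN differed from TIG-1 by -10.4 in YST-1 and -14.9 in HS-PSS on the log2 scale, so its estimate rests mostly on TIG-1 as well. TGM2 also stood 0.92 lower on the log2 scale in the library labelled HS-PSS control than in the YST-1 control. NAPEPLD lies at chromosome 7, 103099776 to 103150001, TGM2 at chromosome 20, 38127385 to 38168475, and TFPI2 at chromosome 7, 93885396 to 93890753.

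Among the fixed lists in the fit without that library, inflammatory cytokines and proteases were lower at 30 µM: 17 of 20 members lay below 0, with a median log2 fold change of -0.71 and a camera adjusted p of 6.72e-05. The adjusted p was 0.556 with an estimated correlation, so the call was lost. Adjusted over the list alone, 4 members fell: the chemokine CXCL8 (-1.93, SE 0.25), PTGS2, the inducible cyclooxygenase (-1.09, SE 0.18), the adhesion molecule ICAM1 (-0.97, SE 0.19) and the cytokine LIF (-0.70, SE 0.20), against 0 over all genes. Targets of FOXO repressed by AKT were higher (camera adjusted p = 0.00297, adjusted p = 0.556 with an estimated correlation), with 5 members that rose adjusted over the list alone, among them TXNIP (0.30, SE 0.08) and CCNG2 (0.28, SE 0.07). YAP and TEAD targets were lower (camera adjusted p = 0.00259, adjusted p = 0.556 with an estimated correlation), with 4 members that fell adjusted over the list alone, among them the coagulation initiator F3 (-0.61, SE 0.16) and CCN2 (-0.40, SE 0.10). Hypoxia and glycolysis genes were lower (camera adjusted p = 7.92e-04, adjusted p = 0.556 with an estimated correlation), with BNIP3 at -0.30 (SE 0.06), and NRF2 targets were higher (camera adjusted p = 0.00259, adjusted p = 0.556 with an estimated correlation), with 19 of 20 members above 0. Fibroblast markers and the Schwann cell lineage list had a camera adjusted p of 0.0438 each (adjusted p = 0.556 with an estimated correlation), with POSTN at 0.65, LUM at 0.52 and PMP22, a myelin protein, at 0.50 (SE 0.09). The value of POSTN rests mostly on TIG-1, as given above. The Schwann cell lineage list was the 1 list called by fry, with a fry adjusted p of 0.0181, and 0.0172 with 9 libraries, and fry called 0 lists when any 1 line was left out. In each library only 4 of the 27 members of that list reached 10 CPM. The AMPA receptor list had 10 of 18 members above 0 and was not called (camera adjusted p = 0.284), and none of its members was called over all genes or over the list alone.

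With all 9 libraries the same contrast called 0 genes in edgeR, 209 at an unadjusted p under 0.05, 3 in DESeq2 and 0 in limma voom, against 4 in edgeR (2 higher, 2 lower) without the library labelled HS-PSS control and 17 (6 higher, 11 lower) without on/off genes as well. With 9 libraries the smallest unadjusted p belonged to NAPEPLD, SCIN (1.72, SE 0.28), GOLGA8R (0.80), TRMT9B (0.76) and LY6G5B (0.66) on the higher side and B4GALT6 (-0.54, SE 0.09), PLAT (-0.65), BNIP3 (-0.39), NAV1 (-0.48) and MDK (-0.51) on the lower, each at an edgeR adjusted p of 0.645. Camera then called 8 lists, with YAP and TEAD targets (median 0.61), metallothioneins (1.61), interferon response (0.59), lysosome and autophagy (0.22) and mitosis (0.17) higher, and cholesterol synthesis (-0.29), neuronal markers (-1.11) and mitochondrially encoded transcripts (-0.28) lower. These calls were lost with an estimated correlation (adjusted p = 0.791 with an estimated correlation). The common dispersion was 0.287 with that library and 0.00509 without it.

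At 10 µM against control over the 3 lines, TMEM158 had a log2 fold change of -0.54 (SE 0.06, adjusted p = 0.0368, edgeR) without the library labelled HS-PSS control, and TGM2 one of -1.19 (SE 0.14, adjusted p = 0.0252, edgeR) with on/off genes also left out. NRF2 targets, genes of the oxidative stress response, were higher: 20 of 20 members lay above 0, with a median of 0.15 and a camera adjusted p of 1.64e-08 (adjusted p = 0.738 with an estimated correlation). Among its members, TXNRD1 stood at 0.18 and NQO1 at 0.35, and none was called adjusted over the list alone. Inflammatory cytokines and proteases were lower (median -0.40, camera adjusted p = 0.00646, adjusted p = 0.758 with an estimated correlation), with CXCL8 at -1.58 (SE 0.24). ATF4 and integrated stress response genes were higher and DNA replication genes lower, with medians of 0.06 and -0.03 (camera adjusted p = 0.0158 and 0.0364, adjusted p = 0.758 with an estimated correlation). With 9 libraries edgeR called 0 genes, with 166 at an unadjusted p under 0.05, 5 in DESeq2 and 0 in limma voom. Leaving out the library labelled HS-PSS control, it called 5 (2 higher, 3 lower), and 3 without on/off genes as well. Both doses share their controls, so their estimates are not independent.

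Set against 10 µM, 30 µM showed no gene that met the naming rule. Without the library labelled HS-PSS control, hypoxia and glycolysis genes were lower at 30 µM, with 23 of 25 members below 0 (median -0.10, camera adjusted p = 4.08e-07, adjusted p = 0.565 with an estimated correlation), and inflammatory cytokines and proteases were lower (median -0.34, camera adjusted p = 3.07e-04, adjusted p = 0.565 with an estimated correlation). ATF4 and integrated stress response genes were lower (median -0.06, camera adjusted p = 3.70e-05, adjusted p = 0.565 with an estimated correlation). Values with the smallest p were WNT5A -0.42 (SE 0.09), CNN1 -0.43, IGFBP3 -0.33 and TFPI2 -0.27 on the lower side and MAGED4B 0.39 (SE 0.09) on the higher, none called. With 9 libraries edgeR called 0 genes, with 19 at an unadjusted p under 0.05, 4 in DESeq2 and 0 in limma voom. In the fit without the library labelled HS-PSS control it called 3 (2 higher, 1 lower), and 1 without on/off genes as well.

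The schwannoma lines alone, 30 µM against control, are the comparison closest to the title of the series. Without the library labelled HS-PSS control and on/off genes, SHMT1, a serine hydroxymethyltransferase of folate metabolism, fell by 1.38 (SE 0.10, adjusted p = 9.21e-09, edgeR) and BHLHE40, a transcriptional repressor of clock and stress genes, by 1.18 (SE 0.11, adjusted p = 3.56e-07, edgeR) on the log2 scale. TGM2 fell by 1.45, the collagen gene COL11A1 by 1.24, the cholesterol transporter ABCA1 by 1.11, GPNMB, a glycoprotein of lysosomes and melanosomes, by 1.08, KAZN by 1.38, VSIR by 1.06, PAEP by 1.03 and GLIPR2 by 0.97. NDE1 rose by 2.00, TRIM27 by 1.72, BASP1 by 1.19, the heparan sulfate proteoglycan GPC1 by 1.03, RGPD5 by 0.94, MDGA1 by 0.93, EIF3CL by 0.92, ZNF704 by 0.82 and TMTC1 by 0.80, and PBX2 also rose (adjusted p = 0.00140, edgeR). In this fit 1 control library stands for the schwannoma lines and is assumed to vary like the others. The spread comes from how far 30 against 10 µM differs between YST-1 and HS-PSS, so these p-values hold no replication of the control. Between the library labelled HS-PSS control and the YST-1 control, SHMT1 differed by -0.82, NDE1 by 1.54 and RGPD5 by 0.87, and TRIM27 had 0 against 637 counts. TGM2, as given above, was also lower in the former, and its level in the YST-1 control was far below that in TIG-1. RGPD5 and EIF3CL have near-identical copies and their counts are uncertain. TRIM27 and PBX2 lie in the MHC region, where on/off genes were more frequent than elsewhere, so their counts are uncertain here and below.

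Lysosome and autophagy genes were lower in this contrast without the library labelled HS-PSS control: 22 of 29 members lay below 0 (median -0.12, camera adjusted p = 1.14e-04), 4 fell over all genes, and 9 fell and 1 rose adjusted over the list alone. Mitosis genes were lower, with 32 of 38 below 0 (median -0.06, camera adjusted p = 1.33e-04), and 0 members were called in edgeR over all genes or over the list alone. DNA replication genes were lower (median -0.05, camera adjusted p = 0.00512), and FOXO targets repressed by AKT were higher (median 0.17, camera adjusted p = 0.00171), with 6 members that rose adjusted over the list alone. These calls were lost with an estimated correlation (adjusted p = 0.825 with an estimated correlation). Mitosis genes in the library labelled HS-PSS control stood above those in the YST-1 control by a median of 0.07.

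In edgeR with 9 libraries this contrast called 0 genes, with 436 at an unadjusted p under 0.05, 310 in DESeq2 and 0 in limma voom. It called 91 (35 higher, 56 lower) without the library labelled HS-PSS control and 238 (105 higher, 133 lower) without on/off genes as well, where the only schwannoma control is that of YST-1, the treated HS-PSS libraries enter through 30 against 10 µM, and 1 residual degree of freedom is left. Without the YST-1 control it called 11783, the treated HS-PSS libraries then being set against the library labelled HS-PSS control. With 9 libraries the smallest p were those of VEGFC, RAB27B, RFTN1, DYNLT3 and CALHM5 (higher) and MDK (-0.67, SE 0.14), DGKD, COL11A1, EFNB1 and CDK7 (lower), with edgeR adjusted p of 0.385 or more. Camera called 7 lists, among them YAP and TEAD targets (median 1.24) and inflammatory cytokines and proteases (median 5.63), lost with an estimated correlation (adjusted p = 0.863 with an estimated correlation). At 10 µM the counts were 0 in edgeR, 436 at an unadjusted p under 0.05, 309 in DESeq2 and 0 in limma voom, 105 (32 higher, 73 lower) without that library, and 267 (84 higher, 183 lower) without on/off genes as well. There TRIM27 rose by 2.15 (SE 0.10), RGPD5 by 1.57, NDE1 by 1.40, SLX1B by 1.26, BASP1 by 1.12, GMPR2 by 1.06, EIF3CL by 1.02, MDGA1 by 0.90, TBC1D19 by 0.82 and TMTC1 by 0.81. The cytokine IL16 fell by 2.05 (SE 0.54), SHMT1 by 1.84 (SE 0.10), NAPRT, an enzyme of NAD synthesis, by 1.49, COL11A1 by 1.39, TGM2 by 1.33, GPNMB by 1.18, BHLHE40 by 1.03, KAZN by 1.02 and HIC1 by 0.98, and NAPRT stood 1.23 lower on the log2 scale in the library labelled HS-PSS control than in the YST-1 control.

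The difference between cell types at 30 µM asked whether the schwannoma lines responded otherwise than TIG-1. Without the library labelled HS-PSS control, lysosome and autophagy genes lay lower relative to TIG-1: 23 of 29 members lay below 0 (median -0.31, camera adjusted p = 1.91e-06), 10 were lower over all genes, and 21 lower and 2 higher adjusted over the list alone. GPNMB differed by -2.20 (SE 0.25), the cholesterol carrier NPC2 by -0.75 and FNIP1 by -0.66. Mitosis genes likewise lay lower, with 34 of 38 below 0 (median -0.21, camera adjusted p = 2.36e-08), 4 lower over all genes and 18 adjusted over the list alone, among them the spindle motors CENPE (-0.46) and KIF11. Both calls were lost with an estimated correlation (adjusted p = 0.983 with an estimated correlation). The chemokine CCL2 differed by 2.35 (SE 0.25), the cytokines IL11 by 1.60 and LIF by 1.06, ICAM1 by 0.81, the keratin KRT18 by 1.51 and ADARB1 by 0.65, all higher relative to TIG-1. Within TIG-1, IL11 and KRT18 stood at log2 ratios of -1.47 and -1.58 at 30 µM, so their differences come mostly from falls in TIG-1. CCL2, LIF, ICAM1 and ADARB1 also fell in TIG-1, as given below. In this fit each side has a single control library, so its calls hold no replication of the controls.

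Without on/off genes as well, the rule for this contrast also took NKD2 (7.86), PBX2 (4.07), GATA3 (3.93) and UNC13A (3.88) on the higher side and NEK11 (-2.68), GEM (-1.76), RPL36A-HNRNPH2 (-1.73) and KAZN (-1.65) on the lower. PBX2 lies in the MHC region and RPL36A-HNRNPH2 is a read-through transcript, and the counts of both are uncertain. With 9 libraries edgeR called 0 genes, with 326 at an unadjusted p under 0.05, 7 in DESeq2 and 0 in limma voom, against 306 (137 higher, 169 lower) without the library labelled HS-PSS control and 704 (333 higher, 371 lower) without on/off genes as well, and 9752 without the YST-1 control. At 10 µM the counts were 0 in edgeR, 313 at an unadjusted p under 0.05, 4 in DESeq2 and 0 in limma voom, and 78 (29 higher, 49 lower) and 221 in the smaller fits. At 10 µM lysosome and autophagy genes differed by a median of -0.29 (camera adjusted p = 1.76e-07, adjusted p = 0.941 with an estimated correlation), with 17 of 29 members lower adjusted over the list alone. The single fibroblast line is assumed to vary like the schwannoma lines, and without that library each side has 1 control library, that of TIG-1 or of YST-1, and the spread comes only from 30 against 10 µM in YST-1 and HS-PSS. Both lines count as schwannoma by their labels alone: SOX10 had 3, 0 and 0 counts in YST-1 and 0 in the treated HS-PSS libraries. In the latter HOXB13, a transcription factor of prostate cells chosen after its values were seen, stood at 8.40 and 8.22 CPM.

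Within TIG-1, the inflammatory cytokines and proteases stood lower in both treated libraries than in the shared control, with medians of -0.49 at 10 µM and -1.17 at 30 µM, each at percentile 0 of the random lists. At 30 µM only 9 members of the list were expressed highly enough to enter. The random lists match mean expression only and take no account of genes that vary together. At 30 µM the ratio to control was 0.277 for CCL2 (95% counting interval 0.233 to 0.329), 0.362 for ICAM1 (0.319 to 0.410), 0.360 for IL11 (0.316 to 0.410) and 0.437 for LIF (0.413 to 0.462). The collagenase MMP1 and stromelysin MMP3 stood at log2 ratios of 0.21 and 0.54. The lysosome and autophagy list had medians of 0.14 and 0.23, at percentile 100 for each dose, with GPNMB at 0.76 and 1.12. The mitosis list had medians of -0.05 and 0.12, at percentiles 0.75 and 100, and the ATF4 and integrated stress response list had 0.15 and 0.03, at percentiles 100 and 73.3. The NRF2 targets stood at 0.13 and 0.08. The largest log2 ratios at 30 µM among genes at 10 CPM or more in both libraries were CEMIP -2.34, SMURF1 -2.07, TGM2 -1.82, KRT18 -1.58 and IL11 -1.47 on the lower side. On the higher side they were INTS3 1.82, PPP1R10 1.78, NDE1 1.46, the calcium-binding protein S100A4 1.39 and FAM180A 1.32, of which INTS3 and PPP1R10 are on/off genes in another line. ADARB1 stood at a ratio of 0.540 (0.495 to 0.589).

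**Figure D3:**
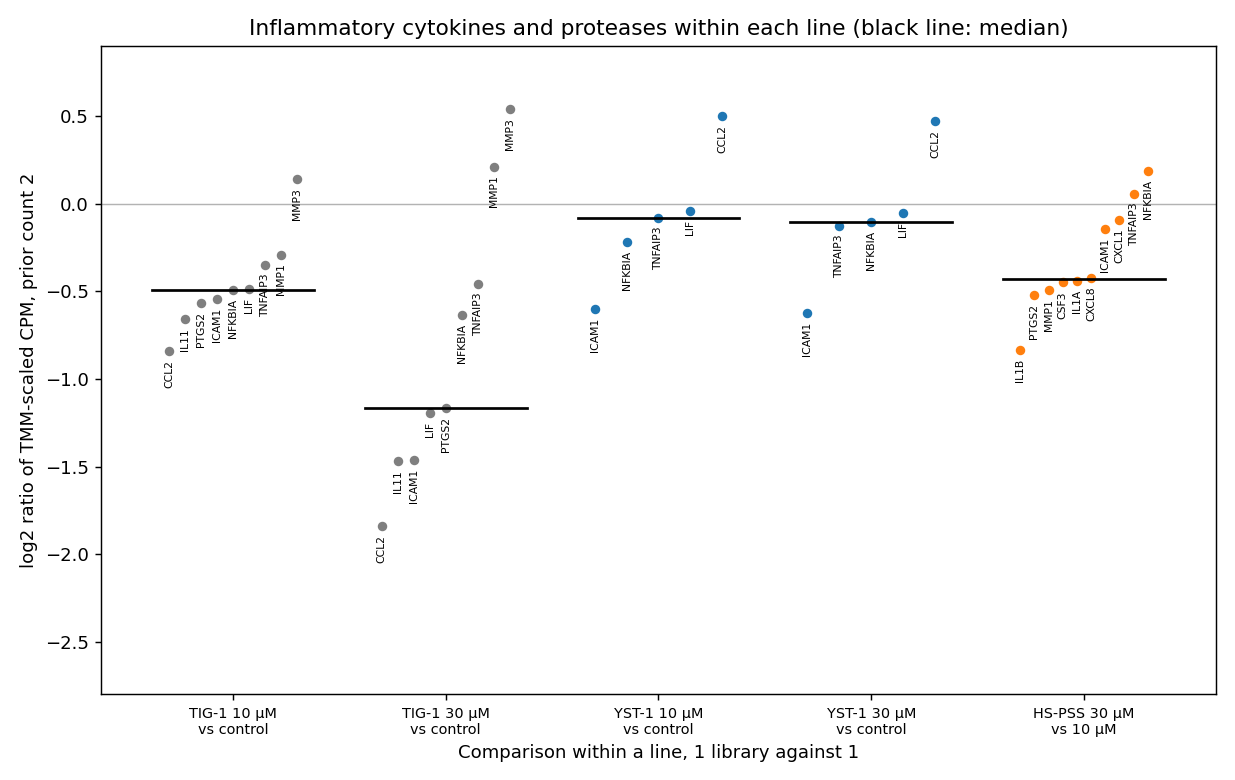
Log2 ratios of the members of the list inflammatory cytokines and proteases in 5 comparisons of 1 library with 1 other, each point a gene at 10 CPM or more in at least 1 of the libraries and the black line their median. The medians are -0.49 and -1.17 in TIG-1 at 10 and 30 µM, -0.08 and -0.10 in YST-1, and -0.43 in HS-PSS at 30 against 10 µM.

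Within YST-1, the lysosome and autophagy list stood lower in both treated libraries than in their shared control, with medians of -0.20 at 10 µM and -0.13 at 30 µM, each at percentile 0. The xenobiotic metabolism list stood higher, with medians of 0.27 and 0.32 at percentile 100. TIPARP and AHRR, targets of the aryl hydrocarbon receptor, had log2 ratios of 0.56 and 0.51 at 30 µM. The hypoxia and glycolysis list had medians of 0.00 and -0.19, at percentiles 35.6 and 0, and that list also stood at -0.08, percentile 0, in the library labelled HS-PSS control against the YST-1 control. The NRF2 targets had medians of 0.14 at 10 µM and 0.00 at 30 µM, with NQO1 at ratios of 1.60 (95% counting interval 1.56 to 1.64) and 1.30 (1.26 to 1.33). The mitosis list stood at -0.01 and -0.06, at percentiles 15.6 and 0.02, and the endothelial markers at -0.17 and -0.16. The list inflammatory cytokines and proteases had medians of -0.08 and -0.10, at percentiles 17.2 and 8.96. Among genes at 10 CPM or more in both libraries, the largest ratios at 30 µM were SHMT1 -1.44, ST3GAL5 -0.89, LAMA4 -0.88, GSDMD -0.75 and DPEP1 -0.74 on the lower side, and NDE1 1.79, TRIM27 1.72, INTS3 1.52, PPP1R10 0.99 and RRN3 0.72 on the higher. PPP1R10 had 407, 0 and 872 counts in YST-1 at control, 10 and 30 µM. INTS3 stood 0.86 higher on the log2 scale in the library labelled HS-PSS control than in the YST-1 control, and INTS3 and PPP1R10 had 878 and 1530 counts in HS-PSS at 10 µM and 0 at 30 µM.

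Within HS-PSS, 30 µM was set against 10 µM, since the library labelled HS-PSS control had the profile described above. The inflammatory cytokines and proteases had a median of -0.43, at percentile 0, with IL1B at a ratio of 0.561 (95% counting interval 0.537 to 0.586), MMP1 at 0.710 (0.688 to 0.732) and CXCL8 at 0.745 (0.712 to 0.780). The interferon response list had a median of -0.22, at percentile 0, with IFIT1 at -0.40, IFIT2 at -0.34 and IFIT3 at -0.25. The mitosis list stood at -0.07, at percentile 0, and the lysosome and autophagy list at 0.05, at percentile 99.8. The largest ratios among genes at 10 CPM or more in both libraries were NDE1 1.13, CTAG1B 0.95, PUF60 0.71, DLG5 0.71 and RNH1 0.67, and DENND11 -1.22, GMPR2 -0.86, IL1B -0.83, CORO7 -0.79 and SLC39A7 -0.78, of which DENND11, CORO7 and SLC39A7 are on/off genes in another line. CTAG1B had 562 counts at 10 µM and 1257 at 30 µM, while its close copy CTAG1A had 426 and 81. Reads divided between these copies can account for part of the ratio of CTAG1B. Against the library labelled HS-PSS control, 4100 genes at 10 µM and 4071 at 30 µM stood 2-fold or more apart, led by RELN, IGF2, SCARA5 and FBLN2 on the lower side and S100A6, THBS1 and NCAM1 on the higher.

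Genes 2-fold or more apart within a line numbered 17 at 10 µM and 60 at 30 µM in TIG-1, 21 and 12 in YST-1, and 12 between 30 and 10 µM in HS-PSS. The library labelled HS-PSS control and the YST-1 control had 10 such genes. The largest of these ratios belonged to genes with 0 counts in 1 of the libraries. In TIG-1 at 30 µM, DCAF15, PANK4, DGKD, TIMM22 and KRTAP1-5 had 728, 548, 531, 447 and 338 counts against 0 in the control, and DENND11, DCAF11, CORO7 and ZBTB22 had 0 against 378, 338, 284 and 231. In YST-1 at 30 µM, SLC39A7 and TIMM22 had 1217 and 937 counts against 0, and DGKD had 0 against 524. For genes at 10 CPM or more in both libraries the numbers were 5 and 26 in TIG-1, 4 and 4 in YST-1, 2 in HS-PSS and 2 between those controls.

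Differences between the lines placed each line by markers of the lineages it could hold, here without the library labelled HS-PSS control. Fibroblast markers were lower in YST-1 than in TIG-1 for 23 of 25 members and lower in HS-PSS than in TIG-1 for 24 of 25. COL1A1, the main fibrillar collagen gene, stood at 32947 CPM in the TIG-1 control, 22.1 CPM in the YST-1 control and 2.73 CPM in HS-PSS at 10 µM. The collagen gene COL1A2 of the same list stood at 2732 CPM in the YST-1 control, where 9 of 25 members reached 10 CPM. Smooth muscle and myofibroblast markers were lower for 12 of 13 members in both YST-1 and HS-PSS. Of the Schwann cell lineage list, 7 of 16 members were higher and 7 lower in YST-1 than in TIG-1, with L1CAM at 5.38 and the myelin gene PMP22 at -5.20 on the log2 scale. In HS-PSS 6 were higher and 8 lower, with NCAM1 at 7.82 and L1CAM at -6.01. SOX2, a transcription factor of immature neural and Schwann cells, stood at 25.1 CPM in YST-1 and 84.0 CPM in HS-PSS at 10 µM and had 0 counts in the TIG-1 control. Endothelial markers were higher in YST-1 than in TIG-1 for 7 of 10 members, with TIE1 at 7.62. Prostate epithelial markers were higher in HS-PSS than in TIG-1 for 4 of 6, with STEAP2 at 2.22.

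The counts of genes called between lines by edgeR were 6800 for YST-1 against TIG-1 (3136 higher, 3664 lower), 3865 for HS-PSS against TIG-1 (1902 higher, 1963 lower) and 0 for HS-PSS against YST-1, the last with 4892 at an unadjusted p under 0.05, 4684 in DESeq2 and 0 in limma voom. They were 12298, 10936 and 12021 (6079 higher, 5942 lower) without the library labelled HS-PSS control. With 9 libraries the fibroblast list had 19 of 25 members lower in YST-1 and 12 of 25 lower in HS-PSS than in TIG-1, and adjusted over the list alone 20 in each. The libraries of a line are its 3 doses, so these p-values hold for these libraries and say nothing of other lines of a cell type.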

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

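All tests of an explanation in this part were chosen only after the result was seen, and the splits of the samples were planned. The library labelled HS-PSS control stood at an SD of 0.0974 from the YST-1 control, and at 0.131 or less from every YST-1 library, where YST-1 libraries stood up to 0.130 apart. These values restate the likeness that raised the question, so they leave a YST-1 library under a wrong label open and give it no support of their own, and the comparison was changed to control against control once the 0.131 was known. A response to the compound that both lines share would move the 639 genes 10-fold apart between that library and HS-PSS at 30 µM, and expressed in YST-1, in YST-1 too. Of them, 0.782% moved 2-fold or more in YST-1 at 30 µM, which argues against a shared response. A response of HS-PSS cells alone would leave YST-1 unmoved, so this test cannot exclude it. Such a response would need untreated HS-PSS cells to match YST-1 as closely as YST-1 libraries match each other. The YST-1 control stood at an SD of 1.00 from the TIG-1 control and 0.0974 from the library labelled HS-PSS control. A wrong label on this control and wrong labels on the treated HS-PSS libraries cannot be told apart: the treated libraries are alike, with an SD of 0.109, and hold the prostate genes HOXB13 (8.40 and 8.22 CPM) and STEAP2 (41.3 and 38.2 CPM), which goes with the tissue label prostate, but no outside profile of either line was used here, and no library was moved to another group.

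Among the TIG-1, YST-1 and treated HS-PSS libraries, with the library labelled HS-PSS control left out, genes with 0 to 3 counts in 1 library of a line and 50 or more in another numbered 69. Of the 48 of these with a position and expression, 10 lie in the MHC region, against 62 of 12132 other expressed genes (odds ratio 51.2, Fisher exact two-sided p = 1.49e-13). Reference assemblies hold this region in several alternative copies, so reads divided among copies of the sequence may underlie part of these counts, while most of the 48 genes lie elsewhere. In TIG-1 and YST-1 the control was the odd library in 42.2% of 64 cases (95% interval 29.9 to 55.2, exact binomial p = 0.145), and a response to the compound cannot be told apart from chance by this share. NAPEPLD, with 0 counts in 3 controls and 84 or more in all 6 treated libraries, is the case in which every library follows treatment, and the same error in every control cannot be told apart from a response.

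The inflammatory cytokines and proteases were lower in TIG-1 at both doses. A scale factor moves all genes of a library alike, so it leaves the gap between the list and all genes unchanged. That gap was -1.19 at 30 µM, where medians of random lists had an SD of 0.0674. The low rank of the list among the same random lists was already known, so this gap restates the pattern and is no separate test of library scaling. RNA of HS-PSS cells in the TIG-1 control would need a share of 71.9%, and the 5 genes chosen as high in HS-PSS and under 1 CPM in TIG-1 at 30 µM, without use of the control, showed a median excess of 0% there, which argues against it; the gene set of this test was changed after a first set had proved unusable, because TIG-1 itself expressed those genes. Another state of the control culture cannot be told apart from an effect of the compound, since there is 1 TIG-1 control library and both doses share it. That the compound lowers these genes in fibroblasts is a hypothesis, and a further control culture could decide it.

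The difference between the schwannoma lines and TIG-1, tested in the model with a dose term per cell type, drew attention to the lists below with all 9 libraries. At 30 µM these were cholesterol synthesis and uptake (median -0.53, camera adjusted p = 0.0191), YAP and TEAD targets (1.58, 1.04e-04), inflammatory cytokines and proteases (6.28, 8.52e-11), metallothioneins (5.54, 0.0131) and mitochondrially encoded transcripts (-0.56, 0.00579). At 10 µM they were other ionotropic glutamate receptor subunits (-1.71, 0.0363), YAP and TEAD targets (1.23, 6.72e-04), prostate epithelial markers (1.41, 0.0363), inflammatory cytokines and proteases (5.42, 1.75e-09), metallothioneins (5.96, 0.0138) and mitochondrially encoded transcripts (-0.56, 0.00137). All of these calls were lost with an estimated correlation (adjusted p = 0.802 or more with an estimated correlation). Without the library labelled HS-PSS control, mitochondrially encoded transcripts at 10 µM kept their call at the fixed correlation only, and the other lists lost theirs. With an estimated correlation no list was called in that fit either. The medians of the inflammatory cytokines and proteases were then 0.81 at 30 µM and 0.56 at 10 µM (camera adjusted p = 0.0857 and 0.155), and those of YAP and TEAD targets 0.10 and 0.05.

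Each comparison of 3 libraries with 3 others has 10 splits, too few for a share under 0.05. The real split and the highest other split called 0 and 161 genes for 30 µM against control over the 3 lines, 0 and 198 for 10 µM against control, 0 and 179 for 30 against 10 µM, 6800 and 0 for YST-1 against TIG-1, 3865 and 2 for HS-PSS against TIG-1, and 0 and 0 for HS-PSS against YST-1. For the line differences with TIG-1, the real split was the only 1 of the 10 with that many genes. The splits with 161 to 198 genes kept 2 of the lines whole on opposite sides, divided the remaining line, and point to the structure of the samples.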

How the results depend on the processing

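The tests without on/off genes, those of 30 against 10 µM within a line, and those of genes at 10 CPM or more in both libraries were chosen only after the result was seen. DESeq2 size factors, no filter on low counts, limma voom, no line term, a linear dose and a fit to the schwannoma libraries alone moved no count of called genes past 1.5 times its value with edgeR. With DESeq2 the counts were 3, 5 and 4 for 30 µM, 10 µM and 30 against 10 µM over the 3 lines, 310 and 309 for the schwannoma lines at 30 and 10 µM, 7 and 4 for the cell type difference, 6109 for HS-PSS against TIG-1 and 4684 for HS-PSS against YST-1; the cause was not tested. Fitting only the 2 doses compared gave 3 genes for 30 against 10 µM. Without the library labelled HS-PSS control and on/off genes the counts were 17, 3, 1, 238, 267, 704 and 221 in the same order, and 12376, 11079 and 12126 for YST-1 against TIG-1, HS-PSS against TIG-1 and HS-PSS against YST-1.

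Leaving out 1 library or line at a time gave 0 to 8 genes for 30 µM (8 without the TIG-1 control, 7 without HS-PSS, 4 without the library labelled HS-PSS control, 1 without the YST-1 control), 0 to 8 for 10 µM (8, 7, 5 and 1) and 0 to 7 for 30 against 10 µM (7 without HS-PSS). The ranges were 0 to 11783 and 0 to 11796 for the schwannoma lines at 30 and 10 µM and 0 to 9752 and 0 to 9748 for the cell type difference, each highest without the YST-1 control. They were 1563 to 12298 for YST-1 against TIG-1, 1247 to 10936 for HS-PSS against TIG-1 and 0 to 12021 for HS-PSS against YST-1, each highest without the library labelled HS-PSS control, and the lowest of 1563 and 1247 came without YST-1 and TIG-1 at 10 µM.

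With an estimated correlation camera called 0 lists in all 7 contrasts, and fry called 0, except 1 for 30 µM over the 3 lines. With so few residual degrees of freedom, the loss of every call with an estimated correlation does not tell the lists apart. Fry also called 1 for the cell type difference at 10 µM without the library labelled HS-PSS control and on/off genes, and it called 0 for 30 µM when any 1 line was left out. Leaving out a line or that library gave 6 to 9 lists for 30 µM, 7 for 10 µM, 0 to 9 for 30 against 10 µM, 5 and 2 for the schwannoma lines at 30 and 10 µM, and 2 and 4 for the cell type difference at 30 and 10 µM. Without on/off genes as well, 8 were called for 30 against 10 µM, 2 for the schwannoma lines at 10 µM and 2 for the cell type difference at 30 µM.

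With a floor of 1 CPM, genes 2-fold apart numbered 150, 279 and 140 in TIG-1 (10 µM, 30 µM, 30 against 10 µM), 110, 103 and 73 in YST-1 and 75 in HS-PSS at 30 against 10 µM. With 10 CPM in both libraries they numbered 5, 26 and 5, then 4, 4 and 2, then 2038 and 1996 against the library labelled HS-PSS control and 2 at 30 against 10 µM; fewer and better counted genes enter. The median of the Schwann cell lineage reversed with a floor of 1 CPM in HS-PSS at 10 and 30 µM against that library (-0.74 and -2.17). Of the values marked as headline results, 104 kept their side of the threshold or moved little under an alternative, and 91 moved. Of the remaining values, 1143 kept their side of the threshold or moved little, 50 passed it under an alternative and 58 moved. The first model already pairs the doses within each line, and no further pairing was run, since the labels give no replicate numbers.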

Other observations

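No tests were run for this part, and the genes and lists in it were chosen only after the result was seen. Lysosome and autophagy genes had ratios of opposite sign in TIG-1 and YST-1, a difference whose test lost its call with an estimated correlation (adjusted p = 0.983 with an estimated correlation at 30 µM and 0.941 at 10 µM). In TIG-1 at 30 µM, GPNMB stood at a log2 ratio of 1.12, the cholesterol carrier NPC2 at 0.53, the calcium channel MCOLN1 at 0.42 and the protease CTSD at 0.32. In YST-1, GPNMB stood at -0.91, FLCN at -0.32 and the protease CTSA at -0.28. The list lysosome and autophagy had 23 members above and 3 below 0 in TIG-1, and 2 above and 21 below in YST-1. Each line has 1 control library, so these values have no replicate check.

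TIPARP, AHRR and CYP1A1, targets of the aryl hydrocarbon receptor, stood higher in both treated YST-1 libraries than in their shared control, TIPARP by 0.60 and 0.56, AHRR by 0.27 and 0.51 and CYP1A1 by 0.28 and 0.32 on the log2 scale at 10 and 30 µM. The read-through transcript PDCD6-AHRR, which overlaps AHRR, had 76, 0 and 25 counts in YST-1 at control, 10 and 30 µM, and AHRR itself had 719, 963 and 1102, so part of its ratios can come from reads divided between these transcripts. TIPARP also stood at 14.3 CPM in the library labelled HS-PSS control, against 11.4 CPM in the YST-1 control. In the list xenobiotic metabolism all 5 expressed members stood above 0 at each dose. NCAM1, PRRX1 and CD68, chosen after their values were seen, stood at 618, 559 and 214 CPM in HS-PSS at 10 µM and at 0, 0 and 14.6 CPM in the YST-1 control. GDF15, a stress-induced cytokine, stood at 109, 62.9 and 67.6 CPM in YST-1 at control, 10 and 30 µM and at 106 CPM in the library labelled HS-PSS control.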
